A study of Mus musculus with 10 samples.

How the data were processed

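RNA was taken from mouse gingival epithelium that had been loosened with the protease Dispase, lifted off with forceps under a microscope and divided into buccal and palatal sides, per the labels' protocols. Polyadenylated RNA was made into stranded libraries with a KAPA kit and sequenced as single-end reads on a NovaSeq instrument, per the labels' protocols. The submitters' processing notes name cutadapt 2.10, TopHat2 2.1.1, HTSeq 2.01, DESeq2 1.36.0 and the genome build GRCm39, with no roles or order. The counting mode and the strand setting are not given in the sources used here.

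The deposited table has, per the file headers, a raw count for each gene and library made by the authors. A further set of columns holds, per the file headers, the authors' DESeq2-normalized values, a signal that was found to equal the count divided by 1 size factor per library. The table names each gene by an Ensembl identifier and a symbol, and 1399 of its 55414 genes have a question mark in place of a symbol. A total of 6250 genes are blank in every library and were left out, which left 49164, of which 19943 had no counts. Small RNAs, mitochondrial ribosomal and transfer RNAs, and immunoglobulin and T cell receptor segments are among the blank genes, so B cell and T cell receptor transcripts were mostly not analysed here. The table has 0 columns of other samples. The reference annotation at hand is of another build than GRCm39, so no coordinates are given.

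Samples were grouped by the tissue label into 5 buccal and 5 palatal libraries. The series' design text speaks of pooled samples from germ-free and specific-pathogen-free mice, a comparison not analysed here. The labels of these libraries name neither status, so the microbial status of the mice is not known. Total counts were 25868777 to 37234192 per library. Tested genes held at least 99.92% of each library's counts. A count of 0 over a group was given a floor of 3 counts, and this floor covers counting error only, since reads without molecular identifiers are not independent molecules.

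Genes were kept by edgeR's filterByExpr with its default minimum count of 10, which left 14062. Libraries were scaled by TMM, and palatal was compared with buccal by edgeR's quasi-likelihood F-test with robust dispersion, two-sided, with Benjamini-Hochberg adjustment at 0.05 (edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 in R 4.3.3). Fold changes are on the log2 scale, palatal minus buccal, and their standard error is the fold change divided by the square root of F. CPM values use the TMM-scaled library sizes, and log2 CPM uses a prior count of 2. On simulated counts for this comparison with 13938 genes tested and 200 changed, the test recovered 81% of genes changed 1.5-fold, 92.7% of those changed 2-fold and 100% of those changed 4-fold, with 7 false calls (3.7% of calls). The changed genes were drawn from those with a mean of at least 1 CPM, so recovery at lower levels was not measured. Far fewer genes changed than were called in the real data, so scaling under a broad difference was not tested. Near-identical gene copies (the Sprr2a genes, Krt6a and Krt6b, the Lce3, Gbp, Oas1 and H2-Q genes) share reads, so the division of counts among them is uncertain.

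Before the data were examined, 37 gene lists holding 980 genes were fixed, along with the tests, the alternatives and the rule for naming genes. The lists cover keratinocyte programs, barrier, immune, signalling, transcription factor and metabolic genes, and markers of other cell types the samples could hold. Of the listed genes 679 were tested, and 36 lists had at least 3 tested members; the mast cell list did not. Lists were tested with camera on log2 CPM with a preset inter-gene correlation of 0.01, with an estimated correlation, and with fry, adjusted over the lists. The mean log2 CPM of each list per library was compared between sides by an exact two-sided permutation test over all assignments of 5 and 5, whose smallest p is 0.00794. Camera called 0 of 35 unchanged lists on simulated data, in which genes vary independently.

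The rule named the 10 genes with the largest positive and the 10 with the largest negative log2 fold change among those past the threshold, with a mean of at least 2 CPM on the higher side and no overlap between the sides, leaving out predicted-gene and clone names. It also named, for each list with a member past the threshold or called by camera, up to 4 members with the smallest p. The text gives those that illustrate each list.

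The alternatives were RLE, upper-quartile and library-total scaling, no filter, a stricter filter (at least 1 CPM in 5 libraries), DESeq2's Wald test, limma-voom with and without sample weights, limma-trend on the deposited normalized values (log2 of the value plus 1), the replicate number as a block, leaving out each library, an FDR of 0.01, and a test against a fold of 1.5. Thinning every library to the smallest total and leaving out number 2 on both sides were added after seeing the data.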

Results

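Polyadenylated RNA was measured in epithelium peeled from mouse gingiva, the gum tissue around the teeth, on the buccal side (facing the cheek) and on the palatal side (facing the palate). There were 10 libraries, 5 from each side. Total counts per library ran from 29317011 to 37234192 in buccal and from 25868777 to 35583168 in palatal samples (exact two-sided permutation p = 0.698). The 10 most abundant genes held 19.1% of counts in buccal and 18.3% in palatal libraries (exact permutation p = 0.143), and mitochondrially encoded genes held 4.37% and 5.07% (exact permutation p = 0.389). The first principal component of log2 CPM carried 67.4% of the variance and placed all 5 buccal libraries on one side and all 5 palatal libraries on the other. Spearman correlations across genes were 0.988 to 0.995 within buccal, 0.991 to 0.997 within palatal and 0.965 to 0.977 between the sides. Every pair of libraries from the same side differed by more than sampling noise, with a chi-square of 8.95 to 69.8 per degree of freedom. The labels do not say that the samples came from separate animals, so p-values measure only the spread between these samples, which may be technical.

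The comparison asked how the epithelium of the palatal gingiva differs from that of the buccal gingiva, the spatial variation that the series title names. Palatal epithelium carried more transcript of the differentiation genes Krt76, Hrnr, Flg and Crnn (log2 fold changes 4.24 ± 0.11, 3.37 ± 0.13, 2.90 ± 0.10 and 5.12 ± 0.16, SE, n = 5 per side). Other differentiation genes fell: of 48 tested cornified envelope and keratinisation genes, 16 were higher and 25 lower. Palatal epithelium carried less of the mucosal keratins Krt4 and Krt13 (-2.07 ± 0.12 and -0.76 ± 0.10), while 4 of 7 mucosal and stress keratins were higher. It also had lower levels of interferon-stimulated genes, of MHC class II genes, of T cell, Langerhans cell and macrophage markers, and of cell cycle genes by camera with a preset correlation. None of these lists was called with an estimated correlation (adjusted p = 0.063 for T and innate lymphoid cell markers and 0.304 for the others). Transcription factors that pattern the head and jaws split by side, with Dlx6, Isl1 and Msx2 higher in palatal and Barx2 and Irx5 higher in buccal samples. Of 14062 genes tested, 5474 (38.9%) passed a false discovery rate of 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2624 higher and 2850 lower in palatal. Of these, 1431 differed at least 2-fold, 609 higher and 822 lower. For 3886 of the genes past the threshold the 5 libraries of one side all lay above the 5 of the other; such separation held for 28.3% of all tested genes, against 0.79% by chance. With a test against a fold of 1.5, 1491 genes passed.

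**Figure D1:**
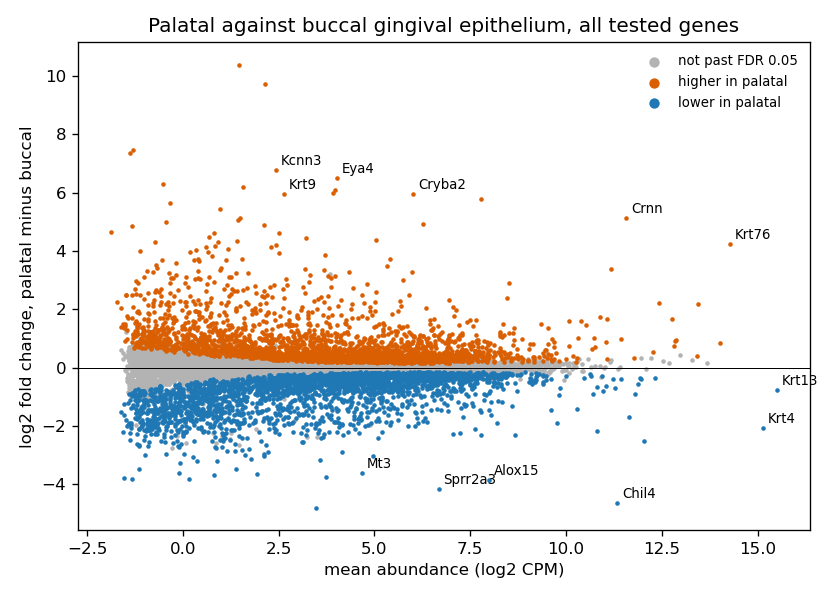
Each point is one of the 14062 tested genes, placed by its mean abundance (log2 CPM) and its log2 fold change, palatal minus buccal; the fitted change of a gene with no counts on one side depends on the prior count. Orange points (2624) were higher and blue points (2850) lower in palatal at FDR 0.05, and Krt76 and Crnn combine a high level with a large difference.

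Among the genes with the largest differences toward palatal were several regulators of transcription. Eya4 (ENSMUSG00000010461) and Eya1 (ENSMUSG00000025932), co-activators of homeodomain factors, were 6.51 ± 0.18 and 5.99 ± 0.15 log2 units higher (SE; edgeR adjusted p = 4.09e-12 and 1.98e-12, n = 5 per side). Their mean levels went from 0.348 to 32.0 CPM and from 0.457 to 29.7 CPM. Isl1, a LIM homeobox factor, was higher by 6.19 ± 0.30 (adjusted p = 9.55e-10) and Dlx6, a distal-less homeobox factor, by 5.45 ± 0.23 (adjusted p = 2.48e-10 in the edgeR test). Kcnn3, a calcium-activated potassium channel gene, rose by 6.76 ± 0.22, Cryba2, a crystallin gene, by 5.96 ± 0.16, and Pacsin1 by 5.06 ± 0.27 log2 units. Krt9, the keratin of palm and sole epidermis, reached 12.2 ± 2.14 CPM (SD, n = 5) in palatal against 0.192 ± 0.0435 CPM in buccal libraries. Crnn, which encodes cornulin, reached 5917 ± 673 CPM against 170 ± 36.8 CPM. Krtap13, a keratin-associated protein gene, had 823 counts over the palatal libraries and 0 over the buccal ones, which makes it at least 283-fold higher with a floor of 3 counts over the buccal group.

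Among the genes with the largest differences toward buccal, the chitinase-like protein gene Chil4 fell by 4.66 ± 0.84 log2 units (SE; edgeR adjusted p = 0.00221, n = 5 per side). Its level was 5002 ± 3694 CPM (SD) in buccal and 197.5 ± 178 CPM in palatal libraries. Alox15, a lipoxygenase gene, fell by 3.85 ± 0.55 (edgeR adjusted p = 5.34e-04), and the small proline-rich genes Sprr2a3, Sprr2i and Sprr2a2 fell by 4.18, 3.74 and 3.68. Without buccal library 2 the log2 fold changes of Sprr2a3 and Sprr2a2 were -3.51 and -2.94 (edgeR adjusted p = 9.62e-04 and 2.13e-05), and without palatal library 2 that of Chil4 was -5.37 (adjusted p = 0.00105). The Sprr2a copies are nearly identical in sequence, so how their reads were divided is uncertain. Abo, the blood group glycosyltransferase gene, fell by 3.64 ± 0.24, Mt3, a metallothionein gene, by 3.62 ± 0.16, Gucy2c by 3.20 ± 0.19, Dclk3 by 3.19 ± 0.19 and Fabp4, a fatty acid binding protein gene, by 3.16 ± 0.36. For all 20 of these genes, the 5 libraries of the higher side lay above all 5 of the lower side, which the naming rule required.

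Keratinocyte differentiation genes moved in opposite directions. Of 48 tested cornified envelope and keratinisation genes, 16 were higher and 25 lower in palatal, with a median log2 fold change of -0.39, and the list as a whole was not called by camera (adjusted p = 0.799). Krt76, a keratin of the suprabasal palate, rose from 1978 ± 159 to 37470 ± 3788 CPM (SD, n = 5; log2 fold change 4.24 ± 0.11 SE, edgeR adjusted p = 3.28e-12). Hrnr, Flg and Flg2, genes of the filaggrin family, rose by 3.37 ± 0.13, 2.90 ± 0.10 and 3.87 ± 0.15. Some listed genes outside the naming rule were picked after their values were seen. Among them Krt10 rose by 2.19 and Ivl by 1.86. Krt1, the usual partner of Krt10, fell by 1.92, Sprr3 by 1.69, Sprr1a by 1.44 and Lor by 0.58 (edgeR adjusted p from 2.74e-09 for Krt10 to 0.00169 for Lor). All 7 mucosal and stress keratins passed the test, 4 higher and 3 lower (camera adjusted p = 0.88). Krt4 fell from 57980 ± 4646 to 13850 ± 2043 CPM and Krt13, its usual partner, from 58480 ± 4708 to 34510 ± 2169 CPM (SD, n = 5). Krt16 and Krt6a, keratins of stressed and hyperproliferative epithelium, rose by 1.66 ± 0.12 and 0.92 ± 0.13, although Krt6a shares reads with the similar Krt6b. Of 22 tested barrier lipid genes, 4 were higher and 11 lower (camera adjusted p = 0.238). Cers4, a ceramide synthase gene, rose by 1.95 ± 0.10 and Sptlc3, of the first step of sphingolipid synthesis, fell by 1.25 ± 0.16.

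**Figure D2:**
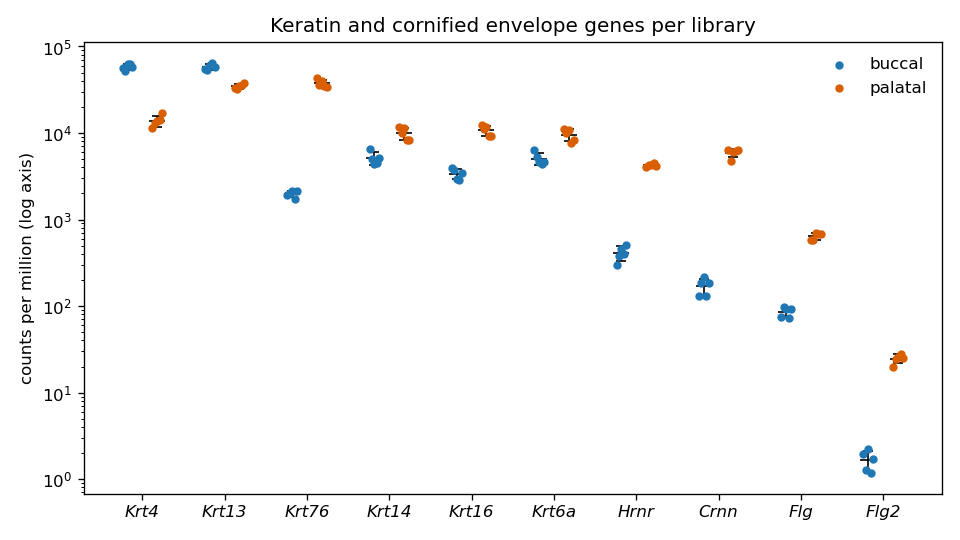
CPM of 10 keratin and cornified envelope genes in each library, on a log axis; points are libraries (5 per side), and bars give the mean and SD. Krt4 and Krt13 are the highest keratins in buccal libraries, and Krt76 rises from 1978 to 37470 CPM in palatal libraries.

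Basal keratinocyte genes were higher in palatal as a list: 10 of 18 rose and 2 fell (3 fell adjusted over the list alone), with a median log2 fold change of 0.32 (camera adjusted p = 0.00715; adjusted p = 0.304 with an estimated correlation). Krt15 rose by 1.48 ± 0.16, Krt14 by 0.96 ± 0.13 and Igfbp2 by 1.04 ± 0.09 in the edgeR fit. Of 32 cell-cell junction genes, 13 rose and 5 fell (16 rose adjusted over the list alone; camera adjusted p = 0.0179; adjusted p = 0.304 with an estimated correlation). The desmosomal genes Dsg1a and Dsc1 rose by 0.98 ± 0.08 and 1.67 ± 0.17, Cldn3 rose by 2.45 ± 0.36, and Pkp2 fell by 2.69 ± 0.29. The junction call was lost when genes needed at least 1 CPM in 5 libraries (camera adjusted p = 0.052). Of 11 simple and junctional epithelium genes, 5 rose and 2 fell, and the list was not called by camera (adjusted p = 0.145). The simple-epithelium keratins Krt8, Krt18 and Krt7 rose by 3.12 ± 0.27, 1.94 ± 0.31 and 1.90 ± 0.28, at mean palatal levels of 4.26, 1.94 and 7.27 CPM.

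Interferon-stimulated genes were lower in palatal. Of 44 tested, 38 fell and 0 rose (41 fell adjusted over the list alone), with a median log2 fold change of -1.90 (camera adjusted p = 3.88e-13; adjusted p = 0.304 with an estimated correlation). Usp18, an interferon-induced deISGylase gene, fell by 1.90 ± 0.23, Xaf1 by 1.63 ± 0.20, Ifi35 by 1.15 ± 0.11 and Irf9, part of the interferon-activated transcription complex, by 0.66 ± 0.07 (edgeR adjusted p from 1.16e-06 for Ifi35 to 3.12e-05 for Usp18). The mean level of the list was 3.99 ± 0.674 log2 CPM in buccal and 2.28 ± 0.505 in palatal libraries (SD, n = 5; exact permutation p = 0.00794, the smallest possible with 5 against 5). Buccal library 2 was the highest of its side at 5.07 log2 CPM and palatal library 2 the highest of its side at 3.10. Of 25 innate sensor genes, 13 fell and 2 rose (camera adjusted p = 0.00183; adjusted p = 0.304 with an estimated correlation). Among them the NOD-pathway kinase gene Ripk2 fell by 1.39 ± 0.09, the inflammatory caspase gene Casp4 by 2.09 ± 0.23, and the nucleic acid sensor genes Ifih1 and Cgas by 1.37 ± 0.15 and 0.62 ± 0.08. All 9 MHC class II presentation genes fell (camera adjusted p = 1.19e-06; adjusted p = 0.304 with an estimated correlation). Cd74 fell from 120.6 ± 29.5 to 33.5 ± 5.54 CPM and H2-Aa from 39.2 ± 9.33 to 11.2 ± 1.62 CPM (SD, n = 5).

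Markers of leukocytes were lower in palatal samples alongside these groups. Of 35 listed T and innate lymphoid cell markers 16 were tested, and all 16 fell, with a median log2 fold change of -1.74 (camera adjusted p = 2.96e-09; adjusted p = 0.063 with an estimated correlation). Cd2 fell by 2.56 ± 0.26, Ctla4 by 2.52 ± 0.26, and the cytotoxic granule gene Nkg7 by 3.47 ± 0.40. Their levels were low, with Cd2 going from 1.12 to 0.182 CPM and Nkg7 from 0.709 to 0.0583 CPM. Genes at such levels could pass the count filter through the buccal side alone, which favours falls among the tested members. The interleukin 7 receptor gene Il7r went from 2.70 ± 0.343 to 0.951 ± 0.110 CPM (SD, n = 5). Of 9 Langerhans and dendritic cell markers 7 fell (camera adjusted p = 4.44e-04; adjusted p = 0.304 with an estimated correlation). Cd207, which encodes langerin, fell from 7.56 ± 1.29 to 1.75 ± 0.294 CPM (SD, n = 5), and another member, Epcam, is also made by keratinocytes. Of 15 monocyte and macrophage markers, 13 fell and 1 rose (camera adjusted p = 4.44e-04; adjusted p = 0.304 with an estimated correlation). Csf1r, the receptor for Csf1 and interleukin 34, fell by 1.31 ± 0.14, and Ptprc, the pan-leukocyte CD45 gene, by 1.64 ± 0.15. Of 9 neutrophil markers 3 rose and 3 fell (4 fell adjusted over the list alone; camera adjusted p = 0.831), with Cxcr2 going from 10.1 ± 1.20 to 3.93 ± 0.466 CPM (SD, n = 5). Of 18 listed B and plasma cell markers 3 were tested, and 1 fell (camera adjusted p = 0.831).

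**Figure D3:**
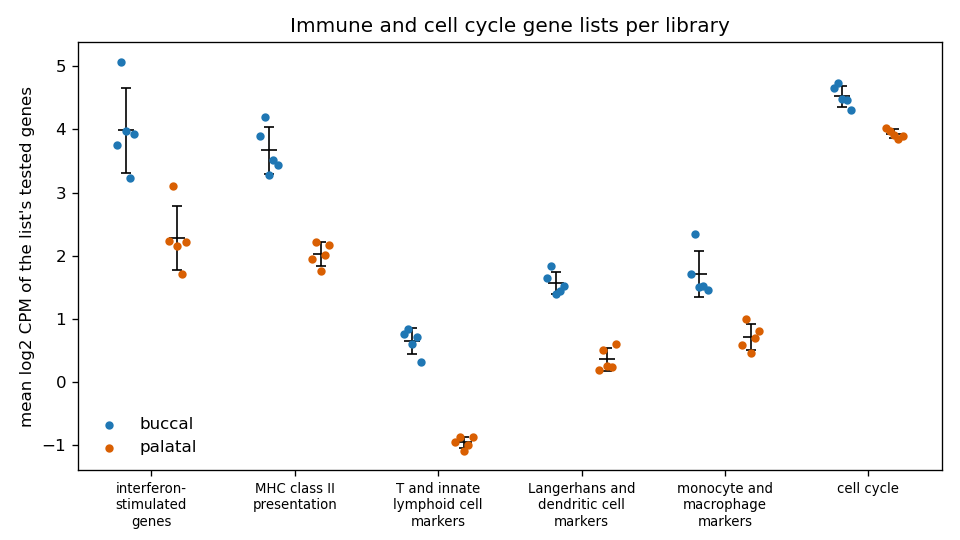
Mean log2 CPM of the tested genes of gene lists in each library; points are libraries (5 per side), and bars give the mean and SD. Interferon-stimulated genes spread most between libraries of a side, with number 2 highest on each, and T and innate lymphoid cell markers average 0.64 in buccal and -0.96 in palatal.

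Secreted immune factors did not move one way. Of 36 inflammatory cytokine and chemokine genes, 7 rose and 8 fell (camera adjusted p = 0.733). Il34, which sustains Langerhans cells, fell by 2.54 ± 0.16 and Il15, a lymphocyte survival factor gene, by 1.81 ± 0.15, whereas the interleukin 36 receptor antagonist gene Il36rn rose by 1.13 ± 0.10. Of 29 antimicrobial effector genes, 6 rose and 9 fell (camera adjusted p = 0.94). Wfdc12 rose by 1.56 ± 0.08, and the peptidoglycan recognition genes Pglyrp3 and Pglyrp4 fell by 0.97 ± 0.11 and 0.87 ± 0.09. Of 13 complement genes, 3 rose and 5 fell (8 fell adjusted over the list alone; camera adjusted p = 0.403), with the complement inhibitor gene Cd55 higher by 1.46 ± 0.14. The TAM list holds receptor tyrosine kinases that restrain inflammation and their ligands, and 1 of its 5 members passed (camera adjusted p = 0.377). Axl fell by 0.79 ± 0.07 (edgeR adjusted p = 3.32e-07), and the ligand gene Gas6 stood at 0.09 ± 0.07 (edgeR adjusted p = 0.339).

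Cell cycle genes and hypoxia and glycolysis genes were lower in palatal as lists. Of 38 cell cycle genes, 34 fell and 1 rose (36 fell adjusted over the list alone), with a median log2 fold change of -0.63 (camera adjusted p = 1.06e-11; adjusted p = 0.304 with an estimated correlation). Ccne1, the cyclin of the G1 to S transition, fell by 1.76 ± 0.17, Top2a by 0.88 ± 0.09, the replication licensing gene Mcm2 by 0.81 ± 0.09 and the spindle gene Nusap1 by 0.78 ± 0.09. The member that rose was Ccnd1, named after its value was seen, by 0.59 ± 0.08. Of 26 hypoxia and glycolysis genes, 15 fell and 2 rose (17 fell adjusted over the list alone; camera adjusted p = 0.00162; adjusted p = 0.304 with an estimated correlation), among them Egln3 by 0.73 ± 0.09 and Hk1 by 0.32 ± 0.06. Of 37 xenobiotic and oxidative stress genes, 18 fell and 6 rose (camera adjusted p = 0.0657). The aldehyde dehydrogenase gene Aldh3a1 fell from 2955 ± 553 to 647 ± 82.6 CPM (SD, n = 5), Gclm fell by 0.90 ± 0.06 and Fmo1 rose by 1.62 ± 0.09. That list passed the camera threshold without buccal library 1 (adjusted p = 0.0406), buccal library 2 (0.0315) or palatal library 5 (0.0466), and with at least 1 CPM in 5 libraries (0.049). Immediate early and heat shock genes, which respond to handling, were mostly not past the test (4 rose and 2 fell of 29; camera adjusted p = 0.94). Of 12 mitochondrially encoded transcripts, 0 passed edgeR's test (1 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma-voom; camera adjusted p = 0.28). Without palatal library 1 or 3 the edgeR test called 1 of these 12.

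TGF-beta and BMP genes and Wnt genes were higher in palatal as lists. Of 33 TGF-beta and BMP genes, 16 rose and 4 fell (camera adjusted p = 0.00193; adjusted p = 0.304 with an estimated correlation). The ligand gene Bmp7 rose from 32.1 ± 2.15 to 130.9 ± 11.8 CPM (SD, n = 5). The BMP target gene Id2 rose by 1.16 ± 0.07 log2 units and the antagonist genes Fst and Bambi by 1.79 ± 0.13 and 1.99 ± 0.15. Of 34 Wnt genes, 17 rose and 6 fell (18 rose adjusted over the list alone; camera adjusted p = 0.0133; adjusted p = 0.304 with an estimated correlation). The stem cell receptor gene Lgr6 rose by 1.80 ± 0.11, the nuclear effector gene Lef1 by 3.95 ± 0.30 and Wnt5a by 0.89 ± 0.08. Wnt16 fell by 2.87 ± 0.26. Notch and hedgehog genes were not called as a list (4 rose and 2 fell of 15; 3 fell adjusted over the list alone; camera adjusted p = 0.673). Of 36 craniofacial regional transcription factors, 18 rose and 9 fell (10 fell adjusted over the list alone; camera adjusted p = 0.15). Msx2 rose from 5.95 ± 0.970 to 79.6 ± 7.27 CPM (SD, n = 5). Barx2 fell from 219.5 ± 21.8 to 44.7 ± 7.20 CPM and Irx5 from 20.4 ± 2.63 to 3.81 ± 0.313 CPM (SD, n = 5; edgeR adjusted p = 6.25e-12, 8.01e-10 and 2.48e-10). Pax9, Nkx2-3 and Pax6 also fell, by 2.23, 2.97 and 2.95, and Barx1, Osr2 and Tbx3 rose by 4.29, 4.12 and 2.44, named after their values were seen.

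Other cell types that a peeled epithelium can carry were compared through their markers. Of 20 fibroblast and matrix markers, 10 rose and 2 fell (11 rose adjusted over the list alone; camera adjusted p = 0.01; adjusted p = 0.217 with an estimated correlation). The proteoglycan gene Dcn rose from 6.61 ± 1.90 to 73.3 ± 6.40 CPM, Col5a2 by 1.52 ± 0.09 and the microfibril gene Fbn1 by 2.91 ± 0.24 log2 units, and Vim fell by 1.95 ± 0.15. Mean levels of the fibrillar collagen gene Col1a1 were 1.87 CPM in buccal and 1.48 CPM in palatal libraries (edgeR adjusted p = 0.405). Of 10 Merkel and taste cell markers 5 rose and 1 fell (camera adjusted p = 0.0155; adjusted p = 0.304 with an estimated correlation). The mechanosensitive channel gene Piezo2 rose by 3.05 ± 0.29 and Atoh1, the Merkel cell determinant, by 2.49 ± 0.33. Isl1, given above among the craniofacial transcription factors, is also in this list, so its rise counts in both. With at least 1 CPM in 5 libraries the list was not called (adjusted p = 0.11). Of 16 skeletal muscle markers 8 fell and 0 rose (1 rose adjusted over the list alone; camera adjusted p = 0.0146; adjusted p = 0.507 with an estimated correlation), among them Neb by 1.93 ± 0.31 and Mb by 1.03 ± 0.20. This call too was lost with at least 1 CPM in 5 libraries (adjusted p = 0.268).

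Of 12 listed melanocyte markers 3 were tested, and 2 rose (camera adjusted p = 0.048, and adjusted p = 0.304 with an estimated correlation). Kit went from 4.34 to 8.84 CPM and Ednrb from 0.335 to 0.950 CPM. The listed pigment genes Dct, Tyr, Tyrp1, Pmel and Mlana did not pass the count filter, and Kit is also in the mast cell list. The melanocyte call did not hold without buccal library 3 (camera adjusted p = 0.05) or 5 (0.0615), nor without palatal library 1 (0.0631), 2 (0.0571), 4 (0.0502) or 5 (0.0575). Markers of ciliated and respiratory epithelium gave 1 higher and 5 lower of 10 (camera adjusted p = 0.0657), and Cyp2f2 fell by 1.47 ± 0.12. The list was called without buccal library 1 (adjusted p = 0.0492) or palatal library 3 (0.0435), and with at least 1 CPM in 5 libraries (0.00349). Of 10 salivary gland markers 3 rose and 2 fell (4 rose adjusted over the list alone; camera adjusted p = 0.831). Ltf, the lactoferrin gene, stood at 114.5 ± 37.3 CPM in palatal and 12.0 ± 9.02 CPM in buccal libraries (SD, n = 5; edgeR adjusted p = 8.29e-04). Of 7 Schwann cell and neuron markers 1 rose, the tubulin gene Tubb3, by 2.08 ± 0.08 (camera adjusted p = 0.235). Of 5 tooth and bone markers 2 rose and 2 fell (camera adjusted p = 0.937). Of 9 endothelial and mural cell markers 2 rose and 2 fell (camera adjusted p = 0.901), and among them Acta2 had a log2 fold change of -0.60 ± 0.21 (edgeR adjusted p = 0.0374) that missed the threshold without buccal library 1, 2 or 3 or palatal library 3, 4 or 5 (edgeR adjusted p from 0.0728 to 0.0977).

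In all, camera called 16 of 36 lists with a preset correlation of 0.01, 7 higher and 9 lower in palatal, and 0 with an estimated correlation, where 3 had an unadjusted p under 0.05. With fry, which tests each list without comparing it with other genes, 23 lists passed. Counts adjusted over the list alone equalled those over all tested genes for 23 of the 36 lists, and differed for the other 13.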

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

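Over 386 groups of 5 values (library totals, shares, list levels and named genes on each side), 25 held a library whose gap to its nearest neighbour was a large part of the range. Chance gives about 1 in 20, so the number flagged is not far from what chance gives. The groups come from the same libraries and partly the same genes, so the flags are not independent. The leukocyte, collagen, gland and thinning tests below were chosen only after the result was seen, and after a first outcome the leukocyte criterion was made stricter and the gland test was replaced.

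Buccal library 2 stood above the other buccal libraries in 10 of these. Its level was 3.56 log2 CPM for innate sensors (others 2.94 to 3.09) and 2.34 for monocyte and macrophage markers (others 1.46 to 1.71). It was also highest for Sprr2i (57.3 CPM against 11.4 to 21.5), Sprr2a2 (8.21 against 1.07 to 2.83), Casp4 (14.2 against 6.22 to 7.37), Ccne1 (5.75 against 4.04 to 4.47), Itgax (8.74 against 4.66 to 5.57), Ly75 (13.2 against 5.63 to 7.53), Ptprc (12.4 against 7.24 to 8.26) and Tyrobp (2.50 CPM against 1.51 to 1.76).

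Buccal library 3 was lowest for TAM receptors and ligands (4.46 log2 CPM, others 4.69 to 4.75) and for craniofacial regional transcription factors (2.64, others 2.72 to 2.75). Buccal library 4 was highest for Dlx6 (0.173 CPM against 0.0532 to 0.0657), Krt7 (4.01 against 1.12 to 1.80) and Ltf (27.5 against 5.25 to 11.6). Buccal library 5 had the largest total of its side (37234192 counts against 29317011 to 31062876) and the highest B and plasma cell marker level (5.38 log2 CPM against 4.99 to 5.09). Palatal library 1 was lowest for Ces1d (15 CPM against 17.7 to 18.1). Palatal library 2 was lowest for Crnn (4750 CPM against 5950 to 6350) and highest for Chil4 (506 against 75.4 to 176) and Tie1 (1.21 against 0.464 to 0.677). Palatal library 4 was lowest for immediate early and heat shock genes (5.54 log2 CPM against 5.91 to 6.05) and highest for skeletal muscle markers (-0.051 against -1.28 to -1.01) and Ttn (0.398 CPM against 0.0957 to 0.132). Palatal library 5 was highest for Pros1 (10.9 CPM against 9.44 to 9.80).

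Interferon-stimulated genes were lower in palatal, with buccal library 2 the highest of all. That library alone is not the source, since 38 of the 44 genes still passed as lower without it, and neither is depth, since 38 passed after every library was thinned to the smallest total. Fewer leukocytes in palatal samples could account for the fall. Interferon-stimulated genes had a median log2 fold change lower than that of 30 pan-leukocyte genes by 0.263 (difference -0.263, 95% bootstrap interval over genes -0.453 to -0.0913), which met the criterion as first written against this explanation. A condition across libraries was then added, and the list level less the leukocyte level gave an exact permutation p of 0.444, so this explanation and a lower interferon response per cell cannot be told apart.

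Matrix genes such as Dcn, Eln and Fbn1 were higher in palatal, and connective tissue carried over with the palatal epithelium would bring fibrillar collagen. The highest upper 95% limit of the log2 fold changes of Col1a1, Col1a2 and Col3a1 was 0.788, against a lower limit of 3.14 for Dcn, and palatal Col1a1 stood at 1.48 CPM against 73.3 CPM for Dcn. This argues against carried-over connective tissue as the source of Dcn. Expression of these genes by palatal epithelium itself, a difference in tissue site, may explain them and was not tested.

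Krt7, Krt8, Krt18 and Krt19 were higher in palatal, and mucous gland cells that carry Muc5b could bring such keratins. Muc5b ran from 1.46 to 5.88 log2 CPM in palatal and from -2.34 to 3.22 in buccal libraries, and with it in the model the mean of the 4 keratins differed by 1.58 log2 units (95% interval 0.87 to 2.28), against 2.14 without it. On the CPM scale the lower 95% limits of the difference for Krt7, Krt8 and Krt18 were 3.07, 1.92 and 0.38, which argues against such gland cells as the whole source of their rise. Other sources stay open and were not tested, among them a site difference in the epithelium and other cell types whose markers rose in palatal. For Krt19 the limit was -0.0725, so gland cells and a site difference cannot be told apart for it with 5 libraries per side. This test replaced one of spans over the palatal libraries, which averaging of genes made void, and Krt19 was set apart after a criterion over all 4 was not met.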

How the results depend on the processing

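The number of genes past FDR 0.05 (5474; 2624 higher and 2850 lower) stayed within 1.5 times under the other scalings, filters and tools run and at an FDR of 0.01. The test against a fold of 1.5, which asks for a larger change, gave 1491 (675 higher and 816 lower). Without 1 library the count ran from 4916 to 5399, with 2348 to 2613 higher and 2516 to 2817 lower. Scaling to library totals moved the share of higher genes from 47.9% to 40.1%. Camera called 15 to 18 lists without 1 library, 23 passed with fry, and 0 were called with an estimated correlation; the cause was not tested. Alternatives chosen after seeing the data gave 5268 genes and 15 lists with libraries thinned to the smallest total, and 5307 genes and 17 lists without the number 2 libraries. Over 154 named genes and all settings run on genes, 3356 of 3369 values kept their direction and their side of the threshold, 9 fell short of it, 4 newly passed and 0 reversed.

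The replicate number as a block gave 5518 genes and 15 lists (2643 genes higher and 2875 lower). Under the block the melanocyte list was not called (camera adjusted p = 0.0582), and no other list call changed. Members past the threshold went from 5 to 8 lower for complement and from 2 to 5 lower for immediate early and heat shock genes. They went from 0 to 1 higher for mitochondrially encoded transcripts, from 1 to 2 higher for Schwann cell and neuron markers, and from 1 to 0 lower for Merkel and taste cell markers. The deviations of same-numbered libraries correlated at -0.02 to 0.34 over 1000 variable genes, and 3 of the 5 exceeded 0.1. The rule set before the fits were compared asked for all 5 over 0.1, so the numbers were not taken to pair the samples. Of 5 libraries on each side, 4 buccal and 3 palatal ones correlated best with their own number, a hint from the data and not the design that some numbers share variation. In a test added after seeing the data, the interferon-stimulated level less the pan-leukocyte level, palatal minus buccal, ran from -0.601 to 0.0844 within numbers (4 of 5 under 0; exact sign-flip p = 0.188, smallest possible 0.0625).

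Of 100 drawn from the 126 splits of the 10 libraries, only the real one (1) gave as many as 5474 genes, and the highest other gave 0. Every other split mixed the sides, so their count of 0 is not a noise level. The result shows only that the real split stood apart from the others drawn in its gene count. For the lists, 5 of the 100 gave 16 or more, the real one included, and the highest other gave 18, so chance cannot be excluded for the number of lists. The 4 other splits with as many each kept 4 of the 5 buccal libraries together and so carried part of the site difference, and the 78 splits that parted them 3 and 2 called at most 15.

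Counts of list members past the threshold moved over 1.5 times without 1 library in these cases. Barrier lipid genes went from 11 to 7 lower without buccal library 4 or 5 or palatal library 1 or 3, and complement genes from 5 to 8 lower without buccal library 4. Immediate early and heat shock genes went from 2 to 5 lower without buccal library 2 or palatal library 3, and from 4 to 2 higher without the latter. Skeletal muscle markers went from 8 to 5 lower without buccal library 5, and also after thinning, and from 0 to 1 higher without buccal library 5 or palatal library 3. TGF-beta and BMP genes went from 4 to 2 lower without buccal library 3 or 5 or palatal library 1, 2, 3 or 5. Salivary gland markers went from 3 to 5 higher without palatal library 1. Other such moves were by 1 or 2 members. With at least 1 CPM in 5 libraries, 4 T and innate lymphoid cell markers were lower in place of 16 (15 after thinning), 2 skeletal muscle markers in place of 8, and 5 cytokine and chemokine genes in place of 8, with 4 higher in place of 7. That filter cut the tested genes from 14062 to 12271, and low members such as Nkg7 (0.709 CPM in buccal) were no longer tested. The smaller counts therefore do not mean that the other members lost their difference. With no filter, 2 complement genes were lower in place of 5 and 2 TGF-beta and BMP genes in place of 4, and 8 Merkel and taste cell markers were higher in place of 5. Other moves under these filters were by 1 or 2 members.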

Other observations

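Further gene groups were listed only after the data were seen, and all of their tests were chosen at that point. Of 23 tested MHC class I presentation genes, 20 were lower and 0 higher in palatal, with a median log2 fold change of -1.53 (camera adjusted p = 2.16e-10; adjusted p = 0.161 with an estimated correlation). Tap1, Psmb8 and Psmb9 are also in the interferon-stimulated list, so these lists are not separate evidence. B2m, the class I light chain gene, went from 680.6 ± 239 to 137.9 ± 27.9 CPM (SD, n = 5). Of 22 sterol biosynthesis genes, 14 were lower and 3 higher (median -0.55, camera adjusted p = 1.18e-05; adjusted p = 0.161 with an estimated correlation). Hsd17b7 and Cyp51 fell by 1.25 and 1.21, whereas Pmvk rose (edgeR adjusted p = 1.23e-08). Of 30 pan-leukocyte genes, 28 were lower and 0 higher (median -1.64, camera adjusted p = 1.55e-15; adjusted p = 0.161 with an estimated correlation).

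Retinoid genes moved in opposite directions, 8 higher and 5 lower of 20 (camera adjusted p = 0.272). Bco1, which cleaves carotene to retinal, rose by 4.48, the retinol binding protein gene Rbp7 by 3.01, Aldh1a1 by 2.61 and the retinol transporter gene Stra6 by 2.21. The retinoic acid receptor gene Rarb fell by 2.45 and the retinoic acid binding protein genes Crabp1 and Crabp2 by 2.63 and 1.44. Of 345 genes named Zfp, 89 were higher and 15 lower (median 0.17, camera adjusted p = 2.27e-05; adjusted p = 0.161 with an estimated correlation).

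Chil4, Alox15 and Sprr2a3, which were among the largest falls in palatal, are known to respond to interleukins 4 and 13 in mouse epithelia, and a weaker response to these cytokines in palatal might explain the fall. Of 21 listed responsive genes, 14 were lower and 2 higher (camera adjusted p = 1.33e-04; adjusted p = 0.167 with an estimated correlation), but many had been seen when the pattern was noticed. In a first version of the test, on all those not named by the rule, 10 of 12 past the threshold were lower (83.3%), which met its criterion. Genes already seen and relatives of the pattern genes were then left out, and of the 12 remaining 7 passed edgeR's test, 5 lower and 2 higher (71.4% lower). Both the share set as needed and the set minimum of 8 genes past the threshold were missed, so the hypothesis stays open, and leukocyte genes such as Fcer2a and Ccl22 are among those that fell.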
